A study of Mus musculus with 12 samples.

How the data were processed

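Bulk RNA-seq was measured in trigeminal ganglia of 12 adult mice, 1 month after injection. Per the labels' protocols, polyadenylated RNA was made into libraries with a TruSeq kit that does not mark strand. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.7.8a and featureCounts 2.0.1, with the mouse genome build GRCm39. The deposited values are raw counts of reads per gene, 1 file per library, with no header and no normalization by the authors. The annotation release and the counting options (overlapping genes, reads that map to several places) are not given in the sources used here.

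Each file holds 55416 Ensembl gene identifiers. Symbols came from the reference tables given for GRCm38, an older build than the one the reads were aligned to, so they were used for names and neighbouring genes only and no coordinate is given. Of the identifiers, 52083 had a symbol and 3333 had none. The latter held 0.274% of all counts. Across the gene lists, 7 entries matched no symbol and were left out.

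The 12 libraries fall into 6 inducible knockouts (iKO) and 6 controls, taken from the labels. All iKO animals carried the Rosa26 CreERT2 allele and 2 floxed Prdm12 alleles and received tamoxifen, which lets the CreERT2 recombinase enter the nucleus. Controls 1 to 4 also received tamoxifen but had at most 1 floxed allele, and controls 2 and 3 lacked Cre. Controls 5 and 6 had the iKO genotype and received corn oil. Among iKO animals 3 were female and 3 male, among controls 2 were female and 4 male. The labels number the replicates 1 to 6 in each group without saying what a shared number means.

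Total counts per library ran from 13207526 to 24178970. A count of 0 in the deepest library allows up to 0.124 CPM, the count scaled to the library's total, and in the shallowest up to 0.227 CPM, taking 3 counts as the limit. These limits cover counting error only, since the reads carry no molecular identifiers. The chi-square per degree of freedom over genes ran from 7.16 to 26.2 in the 30 pairs of libraries of the same group.

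Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, which left 16637, and libraries were scaled with TMM, whose factors ran from 0.969 to 1.02. The quasi-likelihood test used sex as a covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors were taken from the fold change and its F statistic, and confidence intervals are 95% intervals. Levels are given as TMM-normalised CPM, mean ± SD over libraries. Replicates 1 to 4 and replicates 5 and 6 were compared as contrasts in 1 fit with a term for each group and replicate set, which shares the estimate of spread over all 12 libraries. The sex difference of the effect was tested as an interaction. Prdm12 was also tested with an exact two-sided permutation test of the mean log2(CPM + 1) over the 924 assignments of 6 and 6 libraries.

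Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with an estimated correlation, and with fry. There were 41 lists of cell types, pathways and other tissues, written before the data were examined, and the adjusted p-values are over these lists. The tests, covariates, lists and the rule for the genes named were all fixed before the data were examined. The rule names Prdm12 and, where 30 or fewer genes passed, all of them. Where more passed, it takes the 10 largest increases and 10 largest decreases among genes with a mean of at least 1 CPM, and the 10 smallest p-values not yet named. Where fewer than 10 passed, the 10 smallest p-values are given as well. For each list described, members past the threshold are named, up to 4, or otherwise the 2 to 4 with the smallest p. For the comparison of the sexes it takes sex-chromosome genes and the 10 autosomal genes with the smallest p. Some genes the rule takes are not reported here, and no other gene took their place among the genes named by it. Predicted genes without a name were counted but not named unless fewer than 10 other genes passed.

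The tests were tried on simulated counts drawn from the real means and library sizes. Each gene was drawn independently and only genes with a mean of at least 1 CPM were changed. Variation shared between genes, and its false calls, are therefore not covered. In the comparison of all 12 libraries, over 16637 genes, 85% of the genes changed 2-fold and 60% of those changed 1.5-fold were recovered, with 5 false calls. For replicates 1 to 4 these shares were 71% and 56%, for replicates 5 and 6 60% and 20%, for the difference between the replicate sets 44% and 12%, for the sex difference of the effect 50% and 10%, and for male against female 85% and 58%.

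Alternatives were another scaling, no filter or a stricter filter, DESeq2 1.42.0, limma-voom, other covariates including a replicate block and 1 surrogate variable (sva 3.50.0), subsets of the animals, and leaving out each library in turn. A fit without 3 libraries and fits with the mean of a gene list as a covariate were added after the data were seen. Permutation tests were run in scipy 1.17.1.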

Results

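The series asks what losing Prdm12 in adult animals does to gene expression in the trigeminal ganglion, which holds the cell bodies of the sensory neurons of the face. Prdm12 encodes a transcriptional regulator required for the development of nociceptors, the neurons that sense painful stimuli. Read counts per gene were available for 6 iKO and 6 control animals, with total counts of 13207526 to 24178970 per library.

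Prdm12 (ENSMUSG00000079466) was lower in every iKO library than in every control. It measured 16.8 ± 1.97 CPM in iKO and 106 ± 28.4 CPM in controls (mean ± SD, n = 6 each), so that iKO libraries held 15.8% of the control level. The iKO values ran from 13.2 to 19.2 CPM and the control values from 57 to 133 CPM. The difference in mean log2(CPM + 1) was -2.55, with p = 0.00216 in an exact two-sided permutation test, the smallest p that 924 assignments can give. In edgeR the log2 fold change was -2.64 ± 0.185 (SE), with an adjusted p of 2.7e-05. Among the controls, the level was 88.2 CPM in control 1, 118 CPM in controls 2 and 3, 123 CPM in control 4, 133 CPM in control 5 and 57 CPM in control 6. The control mean thus includes control 1, labelled with Cre, 1 floxed allele and tamoxifen, in which that allele could be deleted. Gene-level counts include any exon outside the deleted part, so the level left in iKO does not measure the share of alleles deleted.

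**Figure D1:**
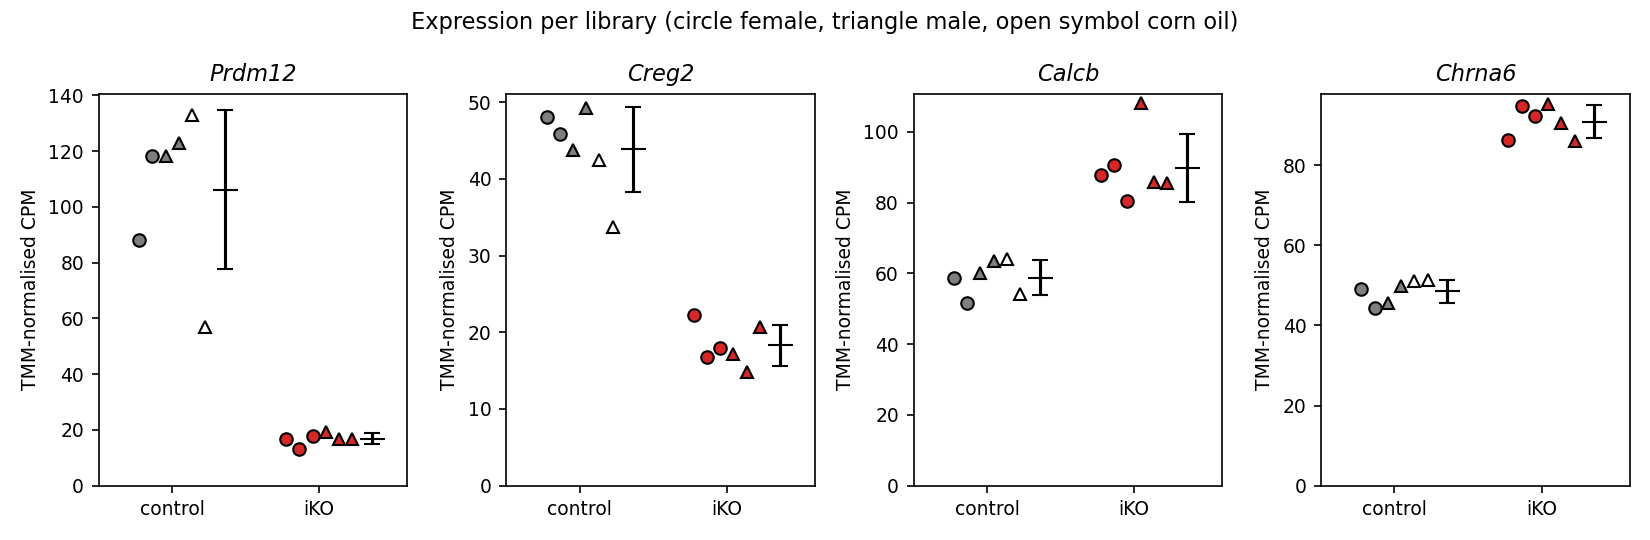
TMM-normalised CPM of Prdm12, Creg2, Calcb and Chrna6 in each of the 6 control and 6 iKO libraries, with the mean and SD of each group as a bar; circles are females, triangles males and open symbols animals given corn oil. Prdm12 lay between 13.2 and 19.2 CPM in iKO and between 57 and 133 CPM in controls, and Chrna6 was higher in all 6 iKO libraries than in any control.

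Across all 12 libraries, 63 genes differed between iKO and control, 29 higher and 34 lower. The nicotinic acetylcholine receptor subunit gene Chrna6 (ENSMUSG00000031491) had the smallest p and rose from 48.5 ± 2.9 to 90.8 ± 4.07 CPM (n = 6 each), a log2 fold change of 0.91 ± 0.049 (SE; edgeR adjusted p = 2.1e-06). Creg2 fell from 43.8 ± 5.57 to 18.3 ± 2.7 CPM, a log2 fold change of -1.28 ± 0.106 (edgeR adjusted p = 0.000135). Calcb, which encodes a form of the neuropeptide CGRP, rose from 58.7 ± 4.93 to 89.7 ± 9.55 CPM, a log2 fold change of 0.63 ± 0.069 (edgeR adjusted p = 0.00166). Most changes were modest: the median absolute log2 fold change of the 63 genes was 0.54, and 11 of them changed by at least 1.

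The dopamine receptor gene Drd1 rose by 1.71 ± 0.24 on the log2 scale from a low level of 0.42 CPM in controls to 1.39 CPM in iKO. The vasopressin receptor gene Avpr1a rose by 0.94 and Rgs9bp by 1.16. Aldh1a3 and Cyp26b1, which encode enzymes that make and break down retinoic acid, rose by 0.73 and 0.68. Skor2, a transcriptional corepressor, rose by 0.71, Atp6ap1l by 0.66, the kinase gene Stk32a by 0.59 and the leukotriene receptor gene Cysltr2 by 0.55. Smaller increases with small p-values were seen for Thsd7b (0.45), Cars (0.43) and Tagln3 (0.27). After Prdm12, the largest decreases were in Insrr (log2 fold change -1.37), a receptor related to the insulin receptor, Creg2 (-1.28) and Smr2 (-1.27). Next came Ranbp3l (-1.22), H2-Q1 (-1.19), Fyb2 (-1.18), the organic anion transporter genes Slc22a8 (-1.12) and Slc22a6 (-1.10), the sulfate transporter gene Slc13a4 (-0.95) and Kcnmb1 (-0.83), a subunit of the BK potassium channel. The kainate receptor gene Grik1 (-0.63), the adenylyl cyclase gene Adcy5 (-0.60), the water channel gene Aqp1 (-0.54) and the nicotinic receptor gene Chrna7 (-0.51) also fell. H2-Q1 belongs to a family of near-identical genes between which reads can be split, so its value is uncertain. With 1 library left out, Ranbp3l (-1.37 to -1.07), H2-Q1 (-1.31 to -1.02) and Slc22a6 (-1.19 to -0.98) were called only without control 4. Slc22a8 (-1.22 to -0.97) was called only without control 4 or 6, Fyb2 (-1.26 to -1.04) only without control 6 or iKO 4, and Cyp26b1 (0.58 to 0.74) only without control 6 or iKO 2. Skor2 (0.66 to 0.72) and Slc13a4 (-0.98) were not called without control 1, control 2 or iKO 1, nor was Rgs9bp (1.07 to 1.14) without these or control 5. Cysltr2 (0.52 to 0.55) was not called without control 1, 2 or 5 or iKO 1, 5 or 6, and Smr2 (-1.22) without control 2. The values in brackets are log2 fold changes where the call was lost.

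In 55 of the 63 genes the 6 iKO values did not overlap the 6 control values, a separation found in 1.2% of all 16637 genes and in 0.22% by chance. The 63 were chosen by their difference in these same libraries, so their separation is not independent support. The unnamed gene Gm13425, chosen here after its values were seen, lies antisense to Prdm12 and overlaps its start in the GRCm38 annotation. It fell from 84.2 ± 10.3 to 52 ± 4.4 CPM, but without strand its reads cannot be told from those of Prdm12. The count of 63 fell to 27 without control 1, 23 without control 2, 33 without control 3, 29 without control 5, 24 without iKO 1, 32 without iKO 5 and 35 without iKO 6. It was 28 in tamoxifen-injected animals, 34 with a replicate block and 333 with DESeq2.

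**Figure D2:**
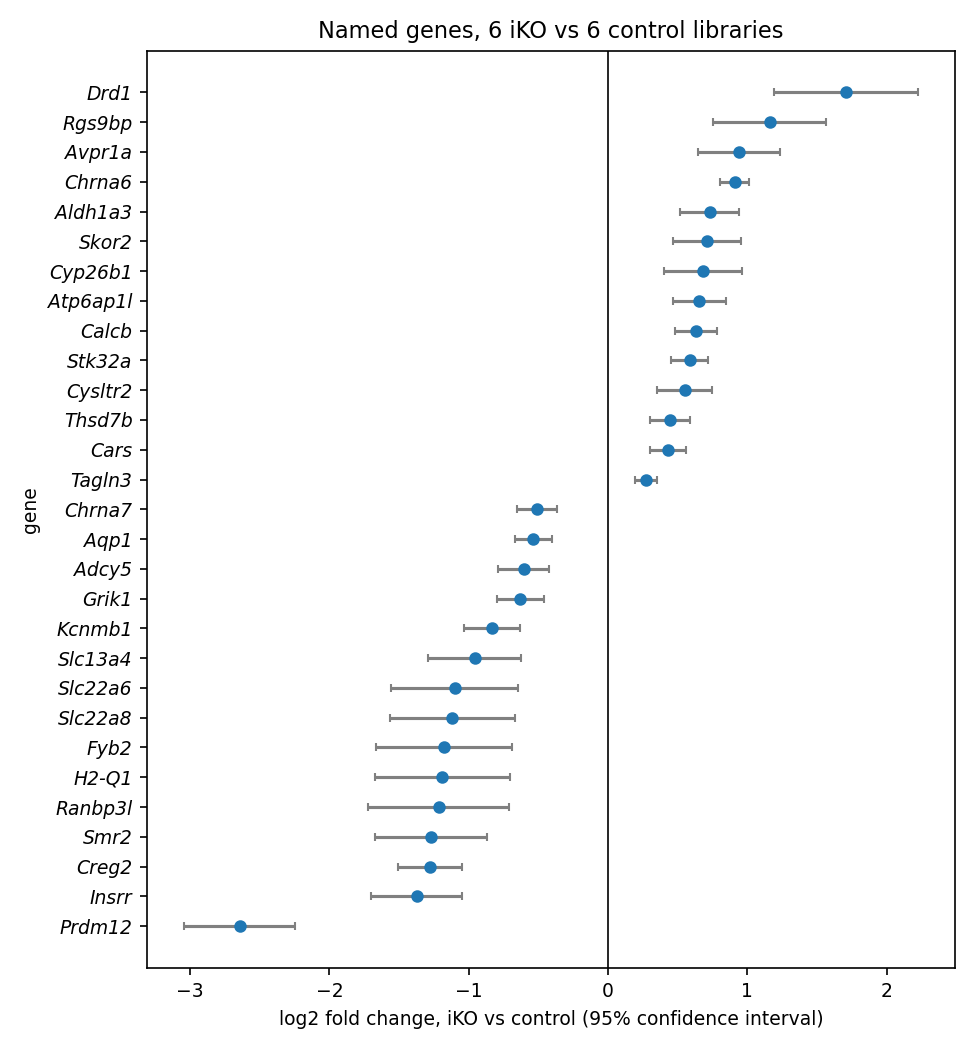
Log2 fold change of each of the 29 named genes between 6 iKO and 6 control libraries on the horizontal axis, with its 95% confidence interval as a bar; the vertical line marks no change. Prdm12 lies at -2.64 and Drd1 at 1.71.

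Markers of pain-sensing neurons moved in different directions. In the list of peptidergic nociceptor genes, 1 of 15 measured members rose and 2 fell past the threshold, and 3 rose and 7 fell when adjusted over the list alone. Calcb rose while Smr2 fell. The list was lower as a whole (camera adjusted p = 0.0017), with adjusted p = 0.437 with an estimated correlation. In the list of nonpeptidergic nociceptors of the Mrgprd type, 1 of 18 measured members rose and 2 fell, or 1 and 3 adjusted over the list alone. The angiotensin receptor gene Agtr1a rose by 0.42 on the log2 scale, Grik1 had a log2 fold change of -0.63 and Wnt2b one of -0.53. This list was lower by camera (adjusted p = 0.000584), with adjusted p = 0.745 with an estimated correlation. No member of the list of cold neurons and C low-threshold mechanoreceptors passed over all genes, and 2 of 8 were lower when adjusted over the list alone, Foxp2 (-0.42) and the cold-sensing channel gene Trpm8 (-0.68). The list was lower by camera (adjusted p = 0.00184), with adjusted p = 0.745 with an estimated correlation.

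Among 60 measured receptor genes known to modulate pain, 2 rose and 4 fell, and 5 and 14 did so adjusted over the list alone. Chrna6 rose. Grik1, Chrna7 and the bradykinin receptor gene Bdkrb2, with a log2 fold change of -0.57, fell. The list was lower by camera (adjusted p = 0.0326), with adjusted p = 0.745 with an estimated correlation. Of 48 voltage-gated potassium and calcium channel genes, 2 fell and none rose over all genes tested, namely Kcnmb1 and Kcna6 (-0.21), and 1 rose and 4 fell adjusted over the list alone. That list was lower by camera (adjusted p = 0.00235), with adjusted p = 0.745 with an estimated correlation. In the itch neuron list 1 of 15 members rose over all genes, Cysltr2, and 4 rose and 2 fell adjusted over the list alone. That list was not called over all 12 libraries with sex as a covariate (camera adjusted p = 0.0807), and was called higher without a covariate (camera adjusted p = 0.0317) and with a replicate block (camera adjusted p = 0.0251). Over all 12 libraries its adjusted p was 0.745 with an estimated correlation, 0.547 in fry's test for change in 1 direction and 5.27e-07 in fry's test for change in either direction, which does not compare a list with other genes.

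The genes shared by sensory neurons in general were not called as a list over all 12 libraries (camera adjusted p = 0.378) but were called lower in tamoxifen-injected animals alone (camera adjusted p = 0.0249), both with the preset correlation. Over all 12 libraries the adjusted p was 0.913 with an estimated correlation, which was not run in the tamoxifen-injected animals alone. None of its 20 members passed, over all genes or over the list alone, and the median log2 fold change was -0.02. Elavl3 had a log2 fold change of -0.24 and Gap43 one of -0.17. None of 21 nociceptor transcription factor genes other than Prdm12 passed in either adjustment, with Hoxd1 at 0.25 and Etv5 at -0.23 (camera adjusted p = 0.313 for the list). No member of 16 voltage-gated sodium channel and partner genes passed over all genes, and 2 were lower adjusted over the list alone, Scn2b (-0.55) and Scn10a (-0.22). The sodium channel list was not called over all 12 libraries (camera adjusted p = 0.0762) but was called lower in tamoxifen-injected animals alone (camera adjusted p = 0.00358) and without control 6, iKO 3 and iKO 6 (camera adjusted p = 0.0342). These used the preset correlation, and over all 12 libraries the adjusted p was 0.745 with an estimated correlation.

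In the list of myelinating Schwann cells, 1 of 20 measured members rose over all genes and 6 rose adjusted over the list alone, and none fell. The myelin protein gene Pmp22 rose from 1865 ± 147 to 2375 ± 164 CPM (n = 6 each), a log2 fold change of 0.36. The list was higher by camera (adjusted p = 5.95e-07), with adjusted p = 0.272 with an estimated correlation. Its mean, centred over libraries, ran from -0.304 in control 3 to 0.188 in control 6. In iKO it ran from -0.045 in iKO 1 to 0.201 in iKO 3, so the groups overlapped. Satellite glia genes were not called (camera adjusted p = 0.979), and none of 18 members passed, with Atp1b2 at -0.60 and Lgi4 at 0.17.

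In the list of fibroblasts and meninges, none of 16 members passed over all genes, and 1 was higher and 8 lower adjusted over the list alone. Ptgds had a log2 fold change of -0.98, with 1347 ± 395 CPM in controls and 691 ± 134 CPM in iKO, and Aldh1a2 one of -0.82. The list was lower by camera (adjusted p = 5.47e-07), with adjusted p = 0.437 with an estimated correlation. Its mean, centred over libraries, ran from -0.145 in control 4 to 0.51 in control 2. In iKO it ran from -0.65 in iKO 6 to 0.255 in iKO 5, so the groups overlapped. In the choroid plexus list, 1 of 7 members fell over all genes, Aqp1, and 1 rose and 5 fell adjusted over the list alone. It was lower by camera (adjusted p = 5.95e-07) and was the only list called with an estimated correlation, with adjusted p = 0.013. Aqp1 measured 214 CPM in controls, where Tmem72 measured 61.8 CPM and Kcnj13 2.16 CPM, and Aqp1 is also made in other cell types.

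Lists of brain, lymphocyte, macrophage, immediate early and skeletal muscle genes were called without any member past the threshold over all genes. Adjusted over the list alone, Camk2a was lower and Myh4 higher, and no other member of these lists passed. Oligodendrocyte and astrocyte genes were called lower in iKO (camera adjusted p = 1.61e-05; adjusted p = 0.745 with an estimated correlation), with Tspan2 at -0.24 and Aldh1l1 at -0.39. The groups overlapped: the mean of the list, centred over libraries, ran from -1.81 in control 4 to 1.91 in control 6. In iKO it ran from -1.81 in iKO 1 to 0.70 in iKO 3. The list was not called in tamoxifen-injected animals alone (camera adjusted p = 0.0804). Brain neuron genes were lower (camera adjusted p = 0.0019; adjusted p = 0.261 with an estimated correlation), with Camk2a at -0.32 and Cbln1 at -0.33. Lymphocyte genes were lower (camera adjusted p = 0.0017; adjusted p = 0.745 with an estimated correlation), with Trac at -0.84 and Pax5 at -1.08. The mean of the lymphocyte list was highest in control 6, at 1.24 on the centred log2 scale, with at most 0.52 in any other library. Without control 6, iKO 3 and iKO 6, a setting chosen after the data were seen, the list was not called (camera adjusted p = 0.333). It was still called in tamoxifen-injected animals alone, a setting that leaves out control 6 too (camera adjusted p = 0.0106). Macrophage genes were lower (camera adjusted p = 0.00226; adjusted p = 0.745 with an estimated correlation), with Cx3cr1 at -0.40 and Cd74 at -0.29. Their mean was highest in control 6 too, at 0.62, and the list was not called without the same 3 libraries (camera adjusted p = 0.439) or in tamoxifen-injected animals alone (camera adjusted p = 0.16). Immediate early genes were lower (camera adjusted p = 0.0107; adjusted p = 0.745 with an estimated correlation), with Zfp36 at -0.58 and Btg2 at -0.34. The mean of that list was below its average over libraries in iKO 1, 2 and 6, at -0.59 to -0.27. It was above it in iKO 3, 4 and 5, at 0.075 to 0.25, and controls ran from -0.10 to 0.36. Skeletal muscle genes were higher (camera adjusted p = 0.0017; adjusted p = 0.745 with an estimated correlation), with Myh4 at 3.34 and Neb at 0.63. Myh4 measured 292 CPM in iKO 5 and 65.5 CPM in iKO 6, and at most 19.3 CPM in any other library.

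**Figure D3:**
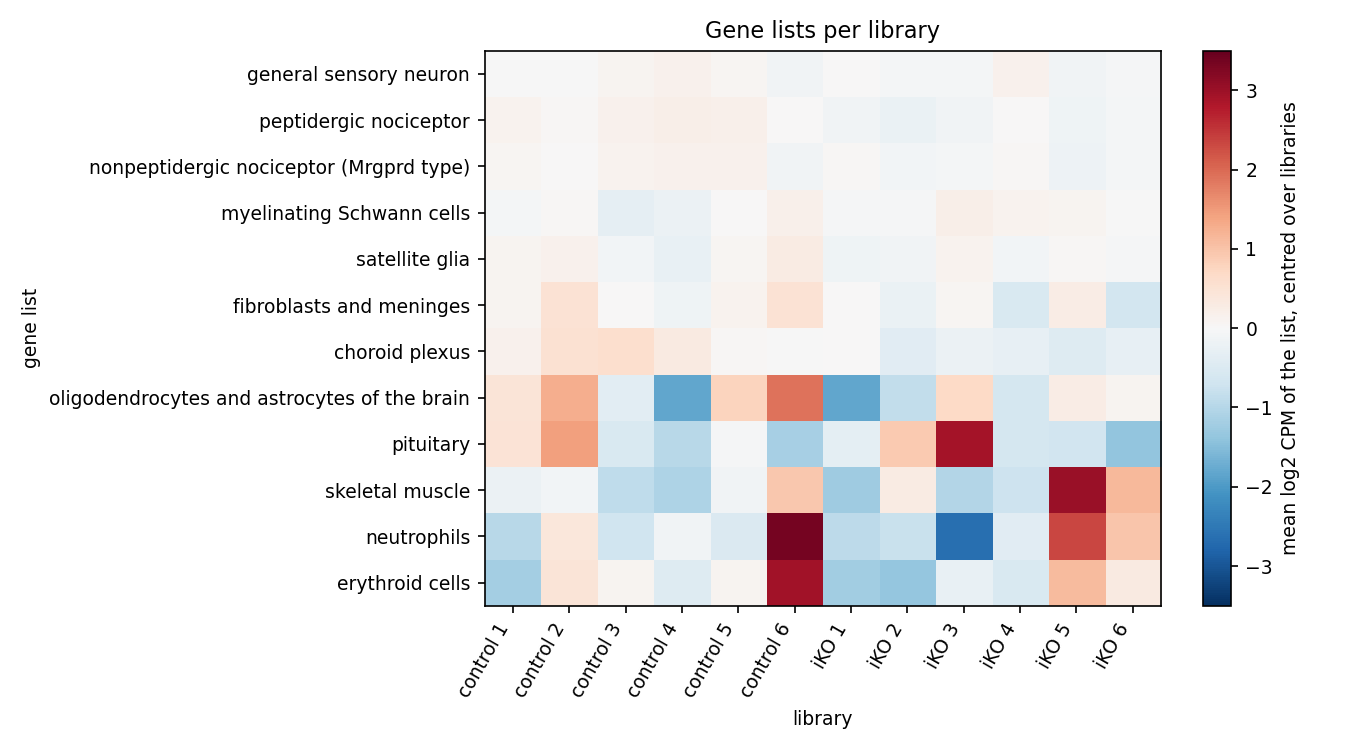
Mean log2 CPM of 12 gene lists, listed down the side, in each library, centred over the 12 libraries, with red above and blue below the mean. The general sensory neuron list varied little, between -0.13 and 0.14, whereas the skeletal muscle list reached 3.02 in iKO 5, the pituitary list 2.91 in iKO 3 and the neutrophil list 3.35 in control 6.

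Within replicates 1 to 4 every animal received tamoxifen, so iKO and control differed in genotype. There, 19 genes differed, 9 higher and 10 lower in iKO (n = 4 each). Chrna6 rose from 47.2 ± 2.69 to 92.1 ± 4.18 CPM, a log2 fold change of 0.98 (edgeR adjusted p = 4.17e-05), and Prdm12 fell from 112 ± 15.9 to 16.8 ± 2.55 CPM, a log2 fold change of -2.67 (edgeR adjusted p = 0.00115). Calcb, Stk32a, Aldh1a3, S1pr3, Pde11a, Thsd7b and Skor2 were other genes that rose, by 0.42 to 0.87 on the log2 scale. Creg2, Insrr, Smr2, Kcnmb1, Grik1, Aqp1 and Chrna7 fell, with log2 fold changes from -1.41 to -0.42, as did Gm13425. The count was 4 without control 1, 5 without control 2, 4 without control 3, 9 without iKO 1, 4 without iKO 3, 2 without iKO 4, and 8 without iKO 5 or iKO 6. With 1 library left out, Chrna6 and Prdm12 kept their calls throughout, and Creg2 (-1.30) and Calcb (0.64) lost theirs without iKO 4. Aldh1a3 (0.78 to 0.98), S1pr3 (0.45 to 0.57) and Stk32a (0.58 to 0.66) were not called without control 1, 2 or 3 or iKO 3 or 4. Kcnmb1 (-0.89 to -0.84) was not called without these or iKO 1 or 2. Chrna7 (-0.47 to -0.39), Grik1 (-0.62 to -0.51) and Pde11a (0.38 to 0.48) were called only without control 5 or 6, Insrr (-1.54 to -1.19) only without these or iKO 1, Skor2 (0.76 to 0.86) only without these or iKO 2, and Aqp1 (-0.60 to -0.54) only without these or iKO 1 or 2. Thsd7b (0.44 to 0.56) was called only without control 6, and Smr2 (-1.52 to -1.26) was never called. The values in brackets are log2 fold changes where the call was lost. The count was 12 when the 8 libraries were fitted alone, 2 with a replicate block and 135 with DESeq2.

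Within replicates 5 and 6 all 4 animals were males of the same genotype, so iKO and control differed in the injection, tamoxifen or corn oil. Chrna6 was the only gene past the threshold in edgeR. It rose from 51.1 ± 0.12 to 88.2 ± 3.19 CPM (n = 2 each), a log2 fold change of 0.79 (edgeR adjusted p = 0.00964). Prdm12 measured 95 ± 53.8 CPM in controls and 16.8 ± 0.15 CPM in iKO, a log2 fold change of -2.49, just outside the threshold (edgeR adjusted p = 0.0509). Next by p, none past the threshold, came Chrna7 (-0.62), Slc13a4 (-1.40), Ky (2.02), Creg2 (-1.10), Actn3 (2.45), Slc22a8 (-1.62), Apobec2 (1.99) and Gab2 (-0.42). Ky and Actn3 are muscle genes, and the mean of the skeletal muscle list, centred over libraries, was highest in iKO 5 (3.02) and iKO 6 (1.13). At an unadjusted p under 0.05 there were 1310 genes. The count was 2 without control 3 or iKO 2, 4 without control 6, 6 without iKO 5 and 26 without iKO 6, and Chrna6 was not called without control 5 (0.78) or control 6 (0.79), where Prdm12 was, at -1.77 and -2.99. DESeq2 called 68 genes, and no gene passed in edgeR when the 4 libraries were fitted alone, with 1385 at an unadjusted p under 0.05.

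The genes found in replicates 1 to 4 were looked up in replicates 5 and 6, with separate fits that share no library. Of the 12 genes called in the first fit, all 12 had the same direction in the second, and 11 passed adjusted over the list alone. They were Prdm12, Gm13425, Chrna6, Creg2, Calcb, Kcnmb1, Grik1, Stk32a, S1pr3, Aldh1a3 and Skor2. All 63 genes called over the 12 libraries had the same sign in both replicate sets, but they were chosen on libraries of both.

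**Figure D4:**
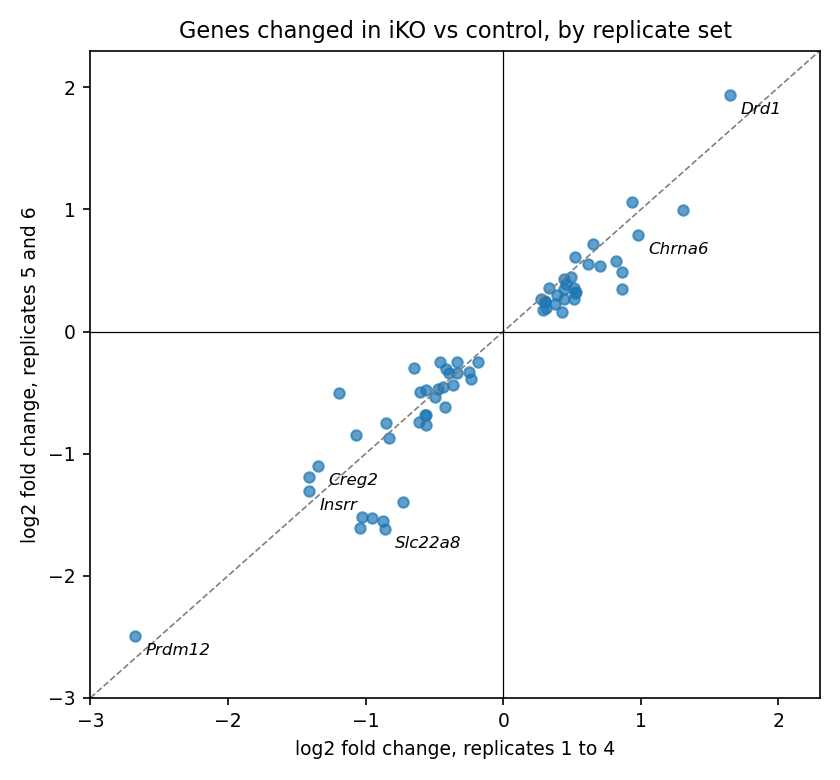
Log2 fold change of the 63 genes called over all libraries, in replicates 1 to 4 on the horizontal axis and in replicates 5 and 6 on the vertical axis, 1 point per gene, with a dashed line at equal values. Prdm12 lies at -2.67 and -2.49, and Chrna6 at 0.98 and 0.79.

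The difference of the iKO effect between the replicate sets was tested directly, since the controls differ in both genotype and injection. No gene passed in edgeR, and DESeq2 called 3, the muscle genes Myl1, Ky and Actn3. At an unadjusted p under 0.05 there were 568 of 16637 genes in edgeR, a share under 0.05. Prdm12 differed by 0.18 on the log2 scale, with a confidence interval from -0.65 to 1.01. The genes with the smallest p in edgeR, none past the threshold, were mostly muscle genes: Ky (2.23), Actn3 (2.57), Mybpc2 (2.53), Myl1 (3.08), Cox8b (3.94) and Eno3 (1.93), beside Itgb6 (1.45), St6galnac2 (1.80), Stoml3 (4.31) and Abi3bp (1.22). Myl1 averaged 27.5 CPM in iKO replicates 5 and 6 and 4.71 CPM in their controls. Without iKO 6 the count was 15.

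The iKO effect did not differ detectably between the sexes. All females were in replicates 1 to 4, and the fit had no term for replicate set, so sex was only partly separated from it. No gene passed the interaction test in edgeR, and none in DESeq2. At an unadjusted p under 0.05 there were 318 of 16637 genes in edgeR, a share under 0.05. Prdm12 differed between males and females by 0.07 on the log2 scale, with a confidence interval from -0.76 to 0.90. The smallest p-values, none past the threshold, belonged to Tbx6 (2.17), C7 (-1.76), Sptssa (0.34), Siglec1 (-1.36), Fam120c (-0.36), Cdh15 (0.67), Bc1 (-2.43), Spock3 (0.34) and Nme2 (0.69), given as the effect in males minus that in females.

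Between 7 males and 5 females, 18 genes differed, 5 higher and 13 lower in males. All females were in replicates 1 to 4, while replicates 5 and 6, which held the animals given corn oil, were all males. The fit had no term for replicate set, so sex was only partly separated from it. Xist, the RNA that silences an X chromosome, measured 473 to 653 CPM in females and 0.54 to 1.9 CPM in males. The Y-linked gene Ddx3y measured 77.6 to 90.6 CPM in males and at most 0.23 CPM in females, and the Y-linked Uty, Kdm5d and Eif2s3y were higher in males too. Each library matched the sex in its labels. The X-linked genes Kdm6a (log2 fold change -0.72), Eif2s3x (-0.63), Kdm5c (-0.52) and Ddx3x (-0.45) were lower in males. Autosomal genes lower in males were Cldn1 (-0.78), Dcn (-0.42), Pomc (-4.84), Igf1 (-0.29), Serping1 (-0.23), Epyc (-0.58) and Lama2 (-0.43), and 2 unnamed genes on the sex chromosomes differed as well, while Smoc2 (-0.57), Abca9 (-0.46) and Endog (0.61) missed the threshold. Pomc is a hormone precursor made in the pituitary. It ranged from 12.6 to 387 CPM in females and from 1.92 to 10.1 CPM in males. Prl, another pituitary hormone gene, measured 16.3 to 1086 CPM in females and at most 17.4 CPM in males, and the mean of the pituitary list was below its average over libraries in all 7 males and reached 2.91 in iKO 3, a female. That mean was also below average in the female iKO 1, at -0.33, lower than in the male control 5, at -0.04. With 1 library left out, Epyc (-0.62 to -0.55) was never called, Igf1 (-0.30 to -0.27) only without iKO 3, Lama2 (-0.45 to -0.37) only without iKO 4 and Serping1 (-0.24 to -0.21) only without iKO 2 or iKO 5. Pomc (-5.09 to -4.59) was not called without control 1, 4, 5 or 6 or iKO 2, 4, 5 or 6, and Dcn (-0.44 to -0.36) without control 2 or 3 or iKO 1, 3, 4 or 6. Ddx3x (-0.45 to -0.40) was not called without control 1, 3 or 5 or iKO 1, 4, 5 or 6, Cldn1 (-0.75 to -0.69) without control 2 or iKO 4, and Eif2s3x (-0.61) without control 1. Abca9 (-0.50) passed without control 6 and Smoc2 (-0.61) without control 4. The count was 11 without control 1 or iKO 6, and 55 with DESeq2.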

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

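In each group of 6 libraries, the named genes of iKO against control and the total counts were screened for a library far from the others of its group. Of 60 such groups 4 held one, where chance gives about 3, or 1 in 20.

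The same library, iKO 4, stood apart in 3 of the 4. Its Chrna7 level was 48.1 CPM, above the 37 to 41.1 CPM of the other iKO libraries and nearer to the controls. Its Calcb level was 108 CPM against 80.5 to 90.6 CPM in the others, and its Cars level 41.7 CPM against 35.8 to 37.8 CPM, both farther from the controls. Prdm12 in iKO 4 was 19.2 CPM, the highest of the 6 iKO libraries but close to the next at 17.7 CPM.

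Among controls, Rgs9bp was 1.79 CPM in control 3 and 0.91 to 1.18 CPM in the other controls, below the mean of 2.65 CPM in iKO.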

How the results depend on the processing

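All 29 genes named for iKO against control kept their direction in all settings. Their call was kept in 403 of 579 gene and setting pairs and in 268 of 348 when 1 library was left out, and was lost in the rest. Chrna6 was called in all 32 settings, between 0.83 and 0.98 on the log2 scale. Prdm12 was called in 30 of 32 settings, DESeq2 and limma-voom among them, from -2.79 to -2.43, but not in the fits of males alone or of animals with 2 floxed alleles alone. By permutation it was past the threshold in each alternative, from -2.71 to -2.47 when 1 library was left out. The count of 63 was 138 with no filter, 333 with DESeq2, 186 with a surrogate variable and 177 at an adjusted p under 0.1. With fewer animals it was 28 (tamoxifen only), 13 (Cre carriers), 1 (2 floxed alleles), 1 (males) and 12 (replicates 1 to 4). Chosen after seeing the data, it was 23 without control 6, iKO 3 and iKO 6, of which 22 were among the 63, 47 with the fibroblast and meninges list mean as a covariate, of which 25 were, and 83 with the oligodendrocyte and astrocyte mean. Leaving out 1 library gave 23 to 88. The 19 genes of replicates 1 to 4 became 621 with no filter, 135 with DESeq2, 12 fitted alone and 2 to 18 without 1 library. The 1 gene of replicates 5 and 6 became 2 with RLE factors, 1014 with no filter, 68 with DESeq2, 0 fitted alone and 1 to 26 without 1 library. The difference between replicate sets gave 578 with no filter, 3 with DESeq2 and 0 to 15 without 1 library. Male against female gave 33 with no filter, 55 with DESeq2 and 11 to 15 without 1 library. The 14 lists called became 1 with an estimated correlation and 1 with fry's test for change in 1 direction. In fry's test for change in either direction, a different question, the adjusted p was 4.9e-09 for pain-modulating receptors, 9.31e-09 for neuropeptides, 1.79e-08 for peptidergic nociceptors, 6.58e-05 for sensory transduction channels, 0.000346 for nonpeptidergic nociceptors, 0.0121 for sodium channels and 0.0328 for nociceptor transcription factors. Lists of other kinds passed this fry test too, among them choroid plexus (adjusted p = 2.74e-05), axon injury (7.28e-05), myelinating Schwann cells (0.000425) and fibroblasts and meninges (0.0031). The looser threshold accounts by construction for 177. The subsets hold fewer animals and other kinds of controls, which were not separated, and for the other settings the cause was not tested. Without 1 library the Prdm12 difference ran from -0.32 to 0.90 between replicate sets and from -0.17 to 0.26 between the sexes, changing sign between sets without control 6 (-0.32) and between sexes without control 2 (-0.17), control 6 (-0.15) or iKO 2 (-0.04), and was not called in any of these.

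A replicate block gave 34 genes, or 15 with sex, in place of 63, 2 in place of 19 for replicates 1 to 4 and 0 in place of 1 for replicates 5 and 6. Deviations of same-numbered libraries correlated at 0.287, 0.124, -0.407, 0.208, -0.065 and 0.187 for numbers 1 to 6, and no control correlated best with the iKO library of its own number. Sex and transcripts of other tissues were not removed from these deviations, so they do not decide whether a shared number pairs the samples. At this depth and number of animals many changes of 1.5-fold would be missed, since 60% were recovered in simulated data.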

Other observations

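The weighing tests in this part were chosen only after the values they concern had been seen. The counts over other splits of the libraries were planned.

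Further genes among the 63, given here with their levels, were chosen after their values were seen. Chrnb3, a nicotinic receptor subunit, rose from 19.6 ± 1.82 to 26.9 ± 2.69 CPM (n = 6 each). The sphingosine-1-phosphate receptor gene S1pr3 rose from 145 ± 10.6 to 194 ± 21.7 CPM, and the thrombin receptor gene F2r from 32.4 ± 4.1 to 42.6 ± 4.12 CPM. The serotonin receptor gene Htr3a fell from 168 ± 13.8 to 125 ± 15.7 CPM, and Cplx2, which acts in vesicle release, from 276 ± 25.6 to 200 ± 17.8 CPM. The tyrosine kinase gene Ptk2b fell from 27.2 ± 3.1 to 17.4 ± 2.04 CPM.

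Several libraries held transcripts of other tissues. The pituitary hormone genes Gh and Prl measured 1316 and 1086 CPM in iKO 3, and 333 and 305 CPM in control 2. S100a9, abundant in neutrophils, measured 522 CPM in control 6 and 6.3 CPM in iKO 3, and the globin gene Hbb-bs 488 CPM in control 6. The mucin gene Muc5ac, chosen after its values were seen, measured 136 CPM in iKO 6 and at most 19.2 CPM elsewhere.

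Other splits of the same libraries into groups of the same size were fitted in the same way. For iKO against control, 2 of 100 splits, the real one included, called at least as many genes as the real 63, a share under 0.05. The 100 were drawn from 462 possible splits, and the median over the others was 0 genes. Since 1 split that mixed the groups called more than the real one, the test does not exclude sources of the count other than the groups. The other of the 2 splits called 120 genes, more than the real split, for a reason that was not tested. It set controls 1, 2 and 3 with iKO 1, 2 and 6, so 3 controls and 3 iKO stood on each side. That side held 4 of the 5 females and 5 libraries of replicates 1 to 4, so the split leaned with sex, which was a covariate, and in part with replicate set. For replicates 1 to 4, 1 of 35 splits, the real one, reached 19 genes, and the highest other called 13. For male against female, 1 of 100 splits, the real one, reached 18, and the highest other called 12. Xist and the Y-linked genes among the 18 mark sex itself and favour the real split in advance, so this count does not bear on the autosomal genes.

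The first pattern weighed is the lower level of Slc13a4, Slc22a6, Slc22a8 and Ranbp3l in iKO, with a median log2 fold change of -1.11. Control 6, iKO 3 and iKO 6 do not carry it alone, since without these 3 libraries the median was -0.95, although none of the 4 genes passed in that fit of fewer samples, with edgeR adjusted p from 0.081 to 0.205. Less meningeal tissue in the iKO samples may account for part of it: with the mean of the fibroblast and meninges list, which holds none of the 4, as a covariate the median was -0.75, from -0.96 to -0.69, and none of the 4 passed, whereas with a surrogate variable the fold changes ran from -1.16 to -0.89 and all 4 passed. Whether the calls ended through smaller fold changes or a wider error was not separated, so this source and an effect of losing Prdm12, which was not tested apart from it, cannot be told apart.

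The second pattern is Prdm12 in control 6, an animal with Cre and 2 floxed alleles given corn oil, at 49.1% of the mean of the other controls. Fewer neurons in that sample do not account for it: the 20 genes of the general sensory neuron list differed by a median of -0.197 on the log2 scale (SD 0.1), far less than Prdm12. Partial deletion without tamoxifen may contribute. Over the 86 other genes called without control 6, it lay a median share of 0.364 of the way from the other controls to iKO. Each other control was placed over the genes called without it, 21 to 67 genes, so the gene sets differ. The highest of them, control 4, lay at 0.22. However, in control 6 the share was 0.509 in the 57 lowered genes and 0.051 in the 29 raised genes. Control 4, with no floxed allele, reached 0.542 in its lowered genes. These genes therefore do not decide whether some alleles were deleted, and partial deletion stays open.

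The third pattern concerns Gt(ROSA)26Sor, the transcript of the locus that carries the CreERT2 allele. It measured 11.1 and 13.6 CPM in the controls labelled as lacking Cre and 4.8 to 8.3 CPM in 9 libraries labelled with Cre, but 13.5 CPM in control 1, which is labelled with Cre. A wrong Cre label for control 1 might explain this. With Cre and tamoxifen the 1 floxed allele of control 1 could be deleted. A right label therefore predicts less Prdm12 than in controls 2 and 3, the other animals with 1 floxed allele, and a wrong label a similar level. Prdm12 in control 1 was 0.746 of the mean of controls 2 and 3. With 1 library on one side and a pair on the other, a wrong label and variation between animals cannot be told apart, and no biological explanation was tested.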
